A study of Mus musculus with 2 samples.

How the data were processed

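Single-cell RNA sequencing of dissociated pancreatic islets was performed on 2 libraries from 4-week-old male mice. One library came from control mice, whose genotype label reads WT while the labels' protocols describe them as carrying the Gcg-Cre driver, and the other from mice in which the coactivator genes Crebbp (encoding CBP) and Ep300 (encoding p300) were knocked out in alpha cells. Each library pooled the islets of 3 mice, per the labels' protocols, with 300 to 400 islets in each group. Libraries were made with the 10x Genomics droplet system, which attaches a barcode to the RNA captured in each droplet, with the version 3 chemistry named in the labels. About 10000 to 15000 cells were loaded per library, per the labels' protocols. Groups were taken from the genotype label, which gave 1 library per group.

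The 4 tables analysed were, for each library, the list of barcodes and the list of genes that label the axes of a raw (unfiltered) feature-by-barcode matrix. The entries of these matrices, the UMI counts per gene and barcode, were not analysed here. Neither kind of table holds a measured value, as inspection of each column showed. Each barcode table has 1 column of sequences of 16 bases with the same suffix, and each gene table has an identifier, a symbol and a feature type. Cell Ranger 5.0.1, STAR, Seurat 4.0.0 and the mm10 genome build are named in the submitters' processing notes, without a role or order. Which gene annotation release was used is not given in the sources used here. The depth of each library is unknown here, and so no level, floor or interval for any gene was computed.

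Barcodes were compared between libraries as exact sequences. Shares of barcodes were given with exact 95% Clopper-Pearson binomial intervals, which cover counting error only. The gene tables were compared row by row. Their identifiers were matched, without version numbers, to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Coordinates are from GENCODE M21, counted from 1. For each gene, the exon count and last exon are those of its APPRIS principal transcript. An overlap was counted where an exon of a listed gene shared at least 1 base with an exon of another listed gene on the same strand. Symbols missing from the gene tables were looked up among RefSeq synonyms of the GRCm38.p6 assembly, used for names alone. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.

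The gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The rule named Crebbp and Ep300 first, then all members of the fixed lists in the gene tables, and then the genes with the largest differences between libraries. Its last part needs counts and was not applied. Some list members are not reported here. The lists, 20 in all, covered the targeted genes, alpha cell identity and secretion, apoptosis and p53, endoplasmic reticulum stress, cell cycle, targets of CREB and cAMP, beta cell genes, and 13 sets of cell type markers. The planned comparisons of cell numbers, cell type shares, the targeted genes, alpha cell genes, the other lists and beta and delta cells all need counts and were not run. With 1 library per group, they would have had no test across samples. The comparison of barcodes by base composition was tested on simulated data. Both of the 2 simulated pairs of lists gave the answer they were made with. The pairs were made with no dependence and with a dependence steeper than that in the data. They do not show how the comparison acts close to its limit.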

Results

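Islet cells of control mice and of mice lacking CBP and p300 in alpha cells were profiled to ask how loss of these coactivators in alpha cells changes the islet transcriptome. Alpha cells are the glucagon-secreting cells of the islet, and CBP and p300 are related histone acetyltransferases that act as transcriptional coactivators. The design holds 2 libraries, 1 per genotype, each pooled from 3 male mice aged 4 weeks. The pooling leaves no replicate within a genotype, so the design gives no test between genotypes. UMI counts were not analysed here. The values below therefore describe which barcodes and genes the 2 libraries list, and no gene or cell type is reported as higher or lower in either genotype.

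The control library listed 1918185 barcodes and the double knockout library listed 1987208, which is 3.60% more. A barcode in an unfiltered list is not a cell. The control list held 128 barcodes for each cell loaded if 15000 cells were loaded and 192 if 10000 were. In the double knockout list these ratios were 132 and 199. The difference of 69023 barcodes between the lists exceeded the number of cells loaded, and it gives no direction for the number of islet cells or of alpha cells. Both lists were free of repeated sequences.

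The 2 lists shared 947698 barcodes. These made up 49.4% of the control list (exact 95% interval 49.3% to 49.5%) and 47.7% of the double knockout list (47.6% to 47.8%). A further 970487 barcodes stood in the control list alone and 1039510 in the double knockout list alone. Every control barcode held 5 to 11 G or C bases. The sharing of sequences does not by itself show mixing of the 2 libraries, and the origin of the shared barcodes was not tested.

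The gene tables of the 2 libraries were identical in all 32286 rows. Both libraries were therefore listed against 1 set of genes, with 32285 Ensembl mouse gene identifiers and 1 added row named tdTomato. A gene in this set need not have been detected in either library. The tdTomato gene encodes a red fluorescent protein widely used as a reporter of Cre recombination, and the mice carried a floxed allele at the ROSA locus, per the labels. Of the Ensembl identifiers, 32235 (99.8%) were found in GENCODE M21 and 50 were not. Among those found, 733 had another symbol there. Protein-coding genes made up 21702 of the 32235 (67.3%), and 13 were encoded by the mitochondrial genome. The next most frequent classes were long intergenic non-coding RNAs with 5605 genes and antisense genes with 2955.

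Both targeted genes were listed. Crebbp (ENSMUSG00000022521) lies on the minus strand of chromosome 16 from 4081328 to 4213997 in GRCm38, a span of 132670 bp. Its principal transcript has 31 exons, and the last of them, which holds the 3′ end, runs from 4081328 to 4086198. Ep300 (ENSMUSG00000055024) lies on the plus strand of chromosome 15 from 81585351 to 81652077, a span of 66727 bp. Its principal transcript also has 31 exons, with the last from 81648802 to 81652077. In GENCODE M21, no exon of either gene overlapped an exon of another listed gene on the same strand. Libraries of this type count RNA mainly from the 3′ end of a transcript. The labels do not name the deleted exons, so a gene-level count of Crebbp or Ep300 need not report the deletion.

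All 120 genes of the fixed lists were present in the gene tables, so each of the 20 lists was complete there. A gene in them could be counted, but need not have been detected. Of the 120, 118 stood under the symbol used in the list. The exceptions were Tmem27, an alpha cell list gene that the tables name Cltrn (ENSMUSG00000015401), and Ero1b, a beta cell list gene that they name Ero1lb (ENSMUSG00000057069). The alpha cell identity and secretion list of 23 genes included Gcg (ENSMUSG00000000394), the gene for proglucagon, on the minus strand of chromosome 2 from 62474530 to 62483650. The beta cell hormone genes Ins1, on chromosome 19 from 52264297 to 52265476, and Ins2, on chromosome 7 from 142678656 to 142743381, were listed as separate genes. The Ins2 interval, 64726 bp, spans all 9 of its annotated transcripts. The markers Sst, the somatostatin gene of delta cells, and Ppy, the pancreatic polypeptide gene, were each listed once.

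Of the fixed genes, 2 had exons in GENCODE M21 that overlapped those of another listed gene on the same strand. The annotation used for counting is not given, and its exons may differ. Ddit3, which encodes the stress-induced transcription factor CHOP and belongs to the endoplasmic reticulum stress list, stood on 2 rows. Its identifiers ENSMUSG00000025408 (chromosome 10, 127290774 to 127296288) and ENSMUSG00000116429 (127290829 to 127293753) overlap in their exons. Reads from the shared part could not be told apart by position alone. Both lie on the plus strand, and the 3′ end of the first lies beyond the second. How many reads fall in the shared part was not measured. Cela2a, an acinar protease gene on chromosome 4 from 141814962 to 141826160, overlapped Ctrc, another acinar protease gene. Over the whole gene table, 38 symbols stood on more than 1 row, covering 78 rows.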

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

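The numbers of barcodes listed in the control and double knockout libraries were the same when repeated rows or the suffix were removed. This could not have come out otherwise, because each list held no repeated row and a single suffix. The gene tables were identical row by row, and so necessarily also as sets of identifiers. Random lists of the same 2 sizes drawn from the union of both lists shared 1289284 barcodes against the 947698 observed. The cause of this gap lies in its construction: the union leaves out every sequence that neither library listed, so it is not an expectation for independent lists, and none is given. The alternatives for cell filters, mitochondrial share, doublets, thinning and scaling all need counts and were not run. No paired analysis was possible because there is 1 library per group and no count was analysed. Depth is unknown, and what it limits cannot be stated. Its bearing on the numbers of barcodes listed and shared was not tested.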

Other observations

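The share of control barcodes that the double knockout list also holds rose with the number of G and C bases among the 16 of the barcode. It was 48.2% (exact 95% interval 47.8% to 48.6%) of 61893 control barcodes with 5 such bases, 49.5% (49.4% to 49.6%) of 512408 with 8, and 50.5% (50.1% to 50.9%) of 65108 with 11. A hypothesis, with its test fixed before this result was seen, is that base composition of the barcode affects this share. It predicted a range of over 2 percentage points between strata of at least 10000 barcodes, and the range was 2.31 points. The intervals of the end strata do not overlap, but the range lies within counting error of the limit set. This is consistent with a small dependence on composition, which may arise in synthesis, amplification or sequencing. These steps were not told apart, the intervals cover counting error only, and no biological explanation was tested. How often possible sequences were listed was not computed.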
